A study of Homo sapiens with 12 samples.

How the data were processed

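Neural crest cells were differentiated from 4 human pluripotent stem cell lines (H9, WTC11, DF19-9-11T and IMR90-4) and transduced with a lentivirus carrying the NOTCH3 intracellular domain and GFP (N3ICD-GFP). Per the labels' protocols, cultures were kept in E6-CSFD medium, dissociated with Accutase and sorted by fluorescence into GFP-negative and GFP-positive fractions 6 days after transduction. RNA was purified on spin columns, enriched for poly(A) RNA and made into libraries with a kit for which the labels state no strand setting. Each line gave 1 library of neural crest cells, 1 of the GFP-negative fraction and 1 of the GFP-positive fraction from matched differentiations, 12 libraries in all. The labels describe sorting only for the 2 fractions taken after transduction.

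The deposited tables hold raw counts and TPM for 43389 named rows, among them a row for eGFP. STAR 2.5.3a, featureCounts of Subread 2.0.3 and the hg38 build are named in the submitters' processing notes, which state neither the annotation nor the strand setting. The deposited counts are whole numbers with a different total in each library, and 2 rows that close the table, a blank row and a row of totals, were left out. The deposited TPM values had been made by the authors from those counts with a single length per gene, as the ratio of both tables showed, and sum to 1000000 in every library. Gene names were matched to RefSeq symbols of the GRCh38.p14 assembly, and 35188 of 43389 names matched. Coordinates are those of that assembly.

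The table lists many genes several times under numbered names, 3771 such rows for 1749 plain names. Of the 759 protein-coding names with numbered copies, 70.4% had fewer than 50 counts over all libraries, against 20.9% of the 18015 protein-coding names without copies. RPS18, a ribosomal protein gene read strongly in most cells, had 1 count in all, and MYH11, the smooth muscle myosin gene, had 0. Low counts of such genes were therefore not read as absence of expression. Of the gene list members, 52 were not tested, and 11 of these have numbered copies, among them MYH11, POU5F1, HES5, NOTCH4, IER3 and HSPA1A. Exons were compared with those of other genes in GENCODE 29. Of the 235 genes found there among those looked up, 2 shared over 50% of their exon bases with another gene, CD68 (85.8%) and DPT (54.6%), and their counts are uncertain. ACTA2 shared 30.1%, in part with an antisense gene, so its reads cannot be assigned to a strand. KRT8 and KRT18 have processed pseudogenes, ACTA2 has close paralogs and NME1 has a close paralog with which reads can be shared.

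Library totals ranged from 15947848 to 21955561 counts. A floor of 3 counts corresponds to 0.137 to 0.188 CPM in a library; such floors and counting intervals cover counting error only. Of the 43389 rows, 30383 had at least 1 count, and 17222 passed edgeR's filterByExpr by group with a minimum count of 10. Differential expression was tested with edgeR 4.0.16 in R 4.3.3 after TMM normalization, with 1 quasi-likelihood fit over all 12 libraries, the line as a block and the group as the factor. A gene passed at an adjusted p under 0.05 by the Benjamini-Hochberg method over all 17222 genes. Log2 fold changes are given with the standard error (SE) of the fit and rest on 4 lines per group. Levels are given as mean TPM ± SD over the 4 libraries of a group. Principal components used log2 CPM with a prior count of 2.

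The line was kept as a block because libraries with the same replicate number come from the same line. Their deviations from the group means correlated at 0.299 to 0.649 in the 12 pairs from the same line and at -0.322 to 0.0962 in the 36 pairs from different lines, across genes. A fit without the block is among the alternatives. Each of the 3 pairs of groups was compared.

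24 gene lists were fixed before the data were examined, and each was tested with camera of limma 3.58.1 on the same fit, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison. Members were counted as higher, lower or not passing over all genes tested and again adjusted over the list alone. Calls with an estimated correlation and with fry are given as alternatives. With the preset correlation, splits of the libraries other than the real one passed up to 10, 14 and 12 lists. A list call alone therefore does not exclude chance. Lists with a median, mean and camera direction of different sign were, against the GFP-negative fraction, the pluripotency genes (median 0.27, mean -0.04), the TGF-beta response genes (median 0.89, mean 0.11, camera downward) and the interferon-stimulated genes (median -0.19, camera upward). Against neural crest they were the unfolded protein genes in GFP-positive cells (median -0.01, mean 0.12) and, in GFP-negative cells, the smooth muscle genes (median -0.27, mean 0.11) and the neuronal genes (median 0.05, camera downward). None of these lists passed in those comparisons.

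Named genes followed a rule fixed before the data were examined. It took NOTCH3, the 8 largest rises and 8 largest falls among genes that passed, had a mean log2 CPM of at least 2 and had the same sign in all 4 lines, up to 4 members of each list that passed, and PDGFRB, RGS5, KCNJ8, ACTA2, TAGLN, PDGFRA, NGFR, SOX10, HES1 and HEYL whatever their p. Clone-type names and genes of the Y chromosome were left out. Folds against a group with no counts are lower bounds from a floor of 3 counts over the group, and folds against 1 to 3 counts are ratios of group totals with exact 95% intervals for counting error.

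The scripts were tested on simulated counts drawn from the means and library sizes of these data, with 100 genes changed by a log2 fold of 1 and 100 by a log2 fold of 2. For GFP-positive against GFP-negative, 20% and 81% of these were called among 16841 genes, with 3 unchanged genes called. For GFP-positive against neural crest, 13% and 78% were called among 16841 genes, with 2 unchanged genes called. For GFP-negative against neural crest, 19% and 82% were called among 16789 genes, with 4 unchanged genes called. A change of 1 on the log2 scale was thus mostly missed in this simulation. Only 200 genes were changed there, so its adjusted p threshold was stricter than with many changed genes. These shares therefore do not carry over to the real comparisons.

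Alternatives were DESeq2 size factors, the Wald test of DESeq2 1.42.0, no filter, a stricter filter, no replicate block, each line left out in turn, a fit to the 8 libraries of the groups compared, limma on log2(TPM + 1) and log2(TPM + 0.1), a test against a log2 fold change of 1, and the other list tests. Left out after seeing the data were the WTC11 neural crest library and, separately, all genes listed several times. Exact splits of the 8 libraries of each comparison were counted, 35 without the line and 8 within lines. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.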

Results

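RNA was sequenced from neural crest cells derived from 4 human pluripotent stem cell lines and from the GFP-negative and GFP-positive cells sorted 6 days after their transduction with N3ICD-GFP. This lentivirus delivers the active intracellular domain of the NOTCH3 receptor together with GFP. Each of the 3 groups held 4 libraries, 1 from each of H9, WTC11, DF19-9-11T and IMR90-4. The labels name the GFP-positive cells mural, the class of vessel-supporting cells that comprises pericytes and smooth muscle cells. Total counts were 20.05 M ± 0.187 (SD, n = 4) in neural crest, 18.67 M ± 2.28 (n = 4) in GFP-negative cells and 17.74 M (1 M is 1000000 counts) ± 1.55 (n = 4) in GFP-positive cells.

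The vector's reporter and its Notch receptor followed the labels. eGFP stood at 3886 TPM ± 709 (SD, n = 4) in GFP-positive cells, 21.3 ± 14.7 (n = 4) in GFP-negative cells and 1.34 ± 2.69 (n = 4) in neural crest. There 3 of 4 libraries had none and the IMR90-4 library had 83 counts. NOTCH3 (gene 4854, chromosome 19, 15159038 to 15200995) stood at 3080 TPM ± 303 (n = 4), 289 ± 133 (n = 4) and 47.4 ± 32.3 (n = 4) in the same order. Its log2 fold change was 3.84 ± 0.49 (SE) between the sorted fractions (edgeR adjusted p = 4.54e-04), 6.24 ± 0.55 for GFP-positive cells against neural crest (edgeR adjusted p = 2.34e-05) and 2.40 ± 0.46 for GFP-negative cells against neural crest (edgeR adjusted p = 0.0022). Counts per gene do not separate vector from endogenous NOTCH3 reads.

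**Figure D1:**
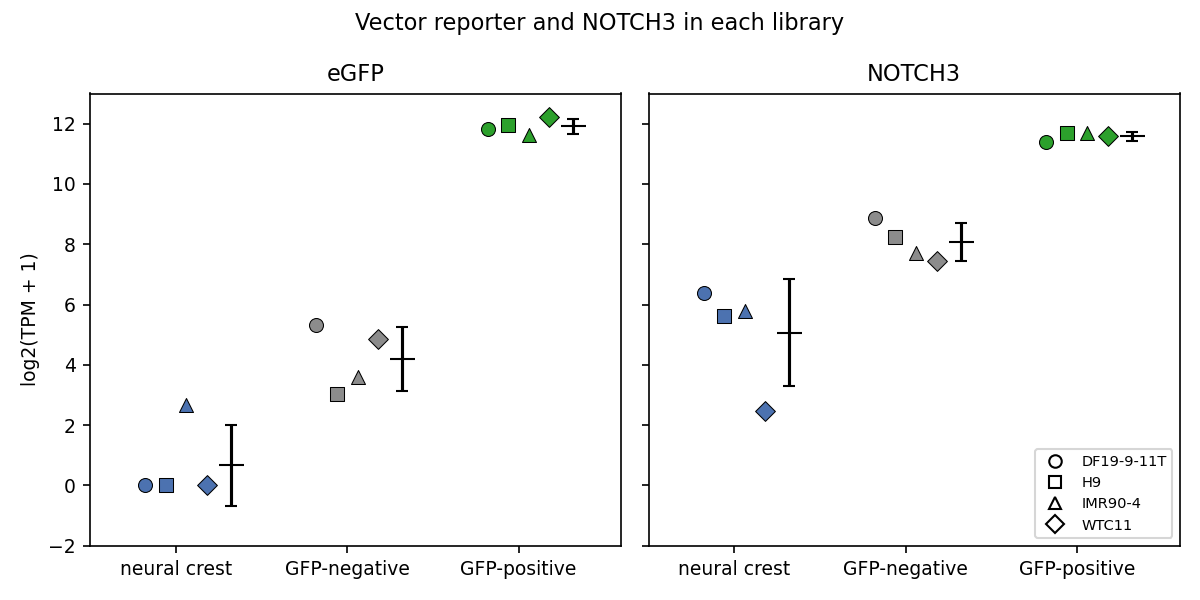
eGFP (left) and NOTCH3 (right) as log2(TPM + 1) in each of the 12 libraries, by group, with 1 symbol per line and the mean ± SD over the 4 lines of a group beside the points. All 4 GFP-positive libraries lie above all others for both genes, with eGFP from 3128 to 4813 TPM.

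The groups separated on the first principal components, which held 44% and 22.1% of the variance of log2 CPM. The WTC11 neural crest library lay at -173.6 on component 1, against -103.9 to -97.8 for the other neural crest libraries. Its TMM factor was 0.649 and 18.9% of its counts came from its top 50 genes, against 10.9% to 12.5% in the other neural crest libraries. NOTCH3 was 4.52 TPM in it and 48.7 to 82.8 TPM in the others.

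**Figure D2:**
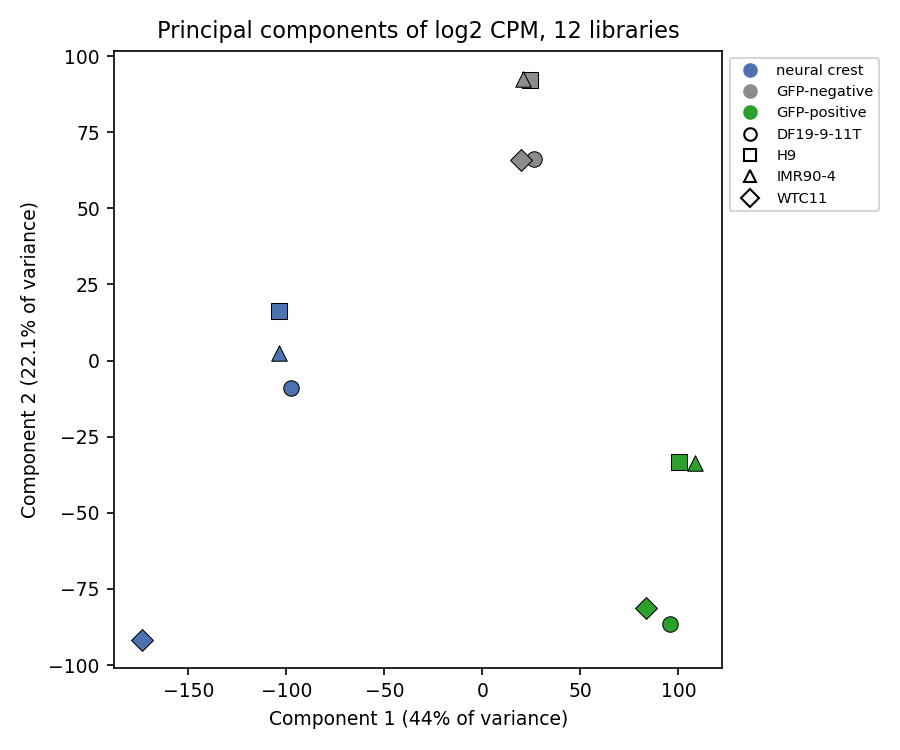
The 12 libraries on components 1 (44% of variance) and 2 (22.1%) of log2 CPM, coloured by group with 1 symbol per line. The groups do not overlap, and the WTC11 neural crest library lies at -173.6 on component 1, apart from the other 3.

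GFP-positive and GFP-negative cells came from the same cultures, and their comparison asks which genes differ between cells with and without the N3ICD-GFP reporter. GFP-positive cells had higher levels of genes that mark pericytes, and far lower PDGFRA, the platelet-derived growth factor receptor of fibroblasts and other mesenchyme. PDGFRA was 45.4 TPM ± 6.4 (n = 4) in GFP-negative and 0.674 ± 0.469 (n = 4) in GFP-positive cells. Of 24 measured pericyte and pan-mural markers, 17 were higher, 1 was lower and 6 did not pass (18 higher and 1 lower adjusted over the list alone). Of 9 measured Notch target genes, 6 were higher, and HES1, a transcriptional repressor that Notch induces in many cells, was lower.

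The mural list had the lowest camera adjusted p (5.55e-24) and was the only list to pass with an estimated correlation (adjusted p = 0.0199). Its largest rises were in GJA4, a connexin of vessel walls (8.05 ± 0.45), TBX2, a T-box transcription factor (7.54 ± 0.53), FOXF2, a forkhead factor of brain pericytes (7.21 ± 0.45), and HIGD1B (6.70 ± 0.41), with edgeR adjusted p from 7.78e-06 to 1.48e-05. RGS5, a regulator of G protein signalling, rose by 4.71 ± 0.65 (edgeR adjusted p = 6.57e-04). KCNJ8, the pore of a potassium channel of pericytes, rose by 3.52 ± 0.25 (edgeR adjusted p = 1.76e-05), and ABCC9, its regulatory subunit, by 5.08. PDGFRB, the receptor through which pericytes are recruited, was 455 TPM ± 132 (n = 4) against 301 ± 35.1 (n = 4), a log2 fold change of 0.79 ± 0.28 (edgeR adjusted p = 0.0723, and 0.0031 without WTC11). The marker that fell was ANPEP, a membrane aminopeptidase (-1.92).

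**Figure D3:**
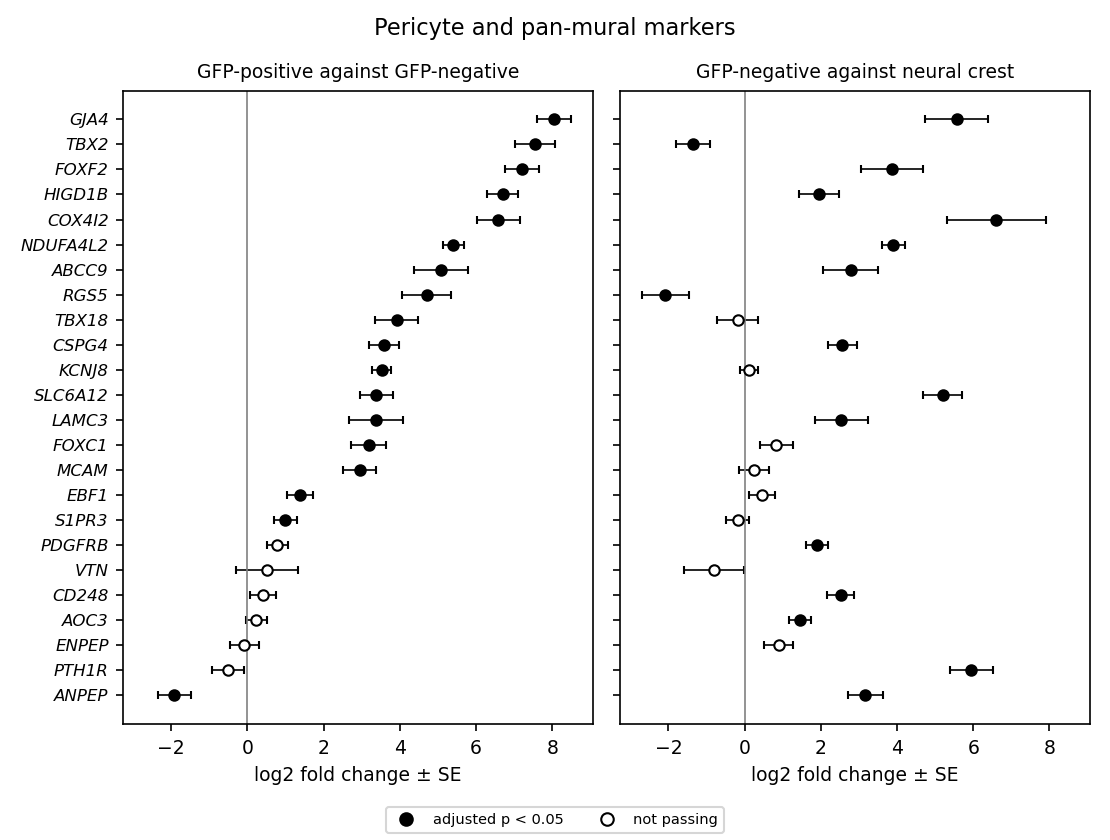
Log2 fold change ± SE of the 24 measured pericyte and pan-mural markers for GFP-positive against GFP-negative cells (left) and GFP-negative cells against neural crest (right), 4 lines per group; filled points passed and open points did not. On the left 17 markers are higher and 1 is lower, and on the right 14 are higher and 2 are lower.

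Among Notch target genes, DTX1 (4.51 ± 0.72), HES4 (3.63 ± 0.38) and NRARP, a feedback inhibitor of Notch (3.56 ± 0.59), rose, with edgeR adjusted p from 1.33e-04 to 0.00201, and HEY2, HEYL and JAG1 rose as well. HEYL (1.89 ± 0.45) did not pass without DF19-9-11T (edgeR adjusted p = 0.0634) or IMR90-4 (edgeR adjusted p = 0.0976). HES1 fell from 1452 TPM ± 980 (n = 4) to 98.3 ± 96.6 (n = 4), a log2 fold change of -3.86 ± 0.76 (edgeR adjusted p = 0.00518). HEY1 was 508 ± 247 (n = 4) and 259 ± 117 (n = 4) TPM and did not pass. The list passed (camera adjusted p = 0.00215, and adjusted p = 0.408 with an estimated correlation). Of 12 other Notch receptors, ligands and modifiers, NOTCH1, DLL4 and DLK1 rose and DLL3, JAG2, MFNG and MAML3 fell. That list did not pass.

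Of 15 measured smooth muscle contractile genes, MYLK, the myosin light chain kinase (4.06 ± 0.47), CALD1, caldesmon (2.23 ± 0.29), SMTN (1.30 ± 0.22) and MYL9 (1.68 ± 0.43) rose and 11 did not pass (7 higher and 1 lower adjusted over the list alone). MYL9 did not pass without DF19-9-11T (edgeR adjusted p = 0.0753). ACTA2, smooth muscle actin, stood at 1.07 ± 0.37 (edgeR adjusted p = 0.0619, and 0.0444 without IMR90-4) and TAGLN at 2.35 ± 0.77 (edgeR adjusted p = 0.0534, and 0.0454 without H9 or 0.0302 without WTC11). The list did not pass (camera adjusted p = 0.0904). PDGFRB (0.0031 without WTC11), ACTA2 and TAGLN passed in a fit to the 8 sorted libraries alone (edgeR adjusted p = 0.00402, 0.00465 and 0.0083) and without the WTC11 neural crest library (edgeR adjusted p = 0.0017, 0.0345 and 0.0225).

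Matrix genes split. Of 16 basement membrane genes, 9 were higher and COL4A6 was lower (camera adjusted p = 8.18e-04, and adjusted p = 0.442 with an estimated correlation). COL18A1 (3.98 ± 0.48), LAMA4, a laminin chain of vessel walls (3.58 ± 0.54), COL4A1 (3.25 ± 0.47) and COL4A2 (2.68 ± 0.46) were the largest, with edgeR adjusted p from 3.23e-04 to 0.00229. Of 21 fibroblast genes, 9 were lower and 6 higher (7 higher and 9 lower adjusted over the list alone), and the list passed downward (camera adjusted p = 0.0181, and adjusted p = 0.408 with an estimated correlation). Without a filter on low counts it did not pass (camera adjusted p = 0.324), and its median went from -0.63 to 0.084. PDGFRA fell by 5.92 ± 0.45, MFAP4 by 4.90 ± 0.63 and FAP, a protease of activated fibroblasts, by 4.19 ± 0.42 (edgeR adjusted p from 2.28e-05 to 4.56e-04), while COL3A1 and COL1A1 rose by 2.71 and 1.24.

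Genes for secreted vascular signals changed in both directions, with 7 of 15 higher and 4 lower (camera adjusted p = 0.00215, and adjusted p = 0.11 with an estimated correlation; 8 higher and 4 lower adjusted over the list alone). ANGPT2, an angiopoietin that acts on endothelium, rose by 8.20 ± 0.57, to 69.3 TPM ± 31.2 (n = 4). PTN rose by 4.60 ± 0.59 and HBEGF by 4.40 ± 0.55, and VEGFD fell by 6.49 ± 0.85, with edgeR adjusted p for the 4 genes from 1.48e-05 to 5.01e-04. In the hypoxia and glycolysis list, 4 of 11 rose (5 adjusted over the list alone; camera adjusted p = 0.0152, and adjusted p = 0.408 with an estimated correlation), the glucose transporter SLC2A1 (5.00 ± 0.45), VEGFA (1.88 ± 0.23), NDRG1 (edgeR adjusted p = 0.053 without DF19-9-11T) and ENO2 (edgeR adjusted p = 0.0585 without IMR90-4). Of 11 cholesterol synthesis genes, 5 rose, among them HMGCS1 (1.27 ± 0.21), MVD (1.09 ± 0.18), INSIG1 and DHCR7, and 6 adjusted over the list alone. That list passed (camera adjusted p = 0.0111, and adjusted p = 0.408 with an estimated correlation). INSIG1 did not pass without DF19-9-11T (edgeR adjusted p = 0.118), H9 (0.0623) or IMR90-4 (0.0619). Nor did DHCR7 without DF19-9-11T (edgeR adjusted p = 0.129), H9 (0.0844) or IMR90-4 (0.0775).

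Neuronal genes were lower in 6 of 12 measured and higher in none (camera adjusted p = 0.00144, and adjusted p = 0.442 with an estimated correlation; 10 lower adjusted over the list alone). NEUROG1 (-6.41 ± 1.11) and NEUROD1 (-6.11 ± 1.41), proneural factors of sensory ganglia, had edgeR adjusted p of 0.00249 and 0.0119. Of 16 neural crest genes, NGFR, the p75 receptor used to mark neural crest, fell by 3.27 ± 0.63 (edgeR adjusted p = 0.00457), along with TFAP2B, TWIST1, SOX5 and PAX7 (edgeR adjusted p = 0.109 without DF19-9-11T and 0.0859 without IMR90-4), while SNAI2 (2.67 ± 0.31) and MSX2 (3.25 ± 0.51) rose. SOX10 stood at -1.26 ± 0.42 (edgeR adjusted p = 0.0551) but passed by DESeq2 (Wald adjusted p = 0.0147) and on log2(TPM + 1) (limma adjusted p = 0.0445). The list did not pass (4 higher and 8 lower adjusted over the list alone). Of 10 epithelial genes, KRT19, GRHL2, ESRP1, KRT5 and TP63 did not pass the count filter and were not tested. All 5 measured epithelial genes were higher (camera adjusted p = 0.00215, and adjusted p = 0.387 with an estimated correlation), the junction genes CDH1, CLDN7 and EPCAM and the keratins KRT8 and KRT18. Of these, CDH1 did not pass without H9 (edgeR adjusted p = 0.111), CLDN7 without H9 (0.103) or IMR90-4 (0.125), and KRT8 (0.0641) and KRT18 (0.0568) without DF19-9-11T.

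Proliferation genes passed upward as a list (camera adjusted p = 0.003, and adjusted p = 0.442 with an estimated correlation), with 4 of 25 higher: RRM2 (1.62 ± 0.27, edgeR adjusted p = 0.00191), MCM4, CDK1 and TPX2, of which the last 3 did not pass without H9 (edgeR adjusted p = 0.0645, 0.0582 and 0.0935). CDK1 and TPX2 also did not pass without DF19-9-11T (edgeR adjusted p = 0.0551 and 0.0996) or IMR90-4 (edgeR adjusted p = 0.06 and 0.098). The immediate early and heat shock list (FOSB, JUN and ATF3 of 11, 4 adjusted over the list alone, camera adjusted p = 0.0447) and the unfolded protein list (TRIB3, XBP1 and PDIA4 of 11, camera adjusted p = 0.0347) also passed upward. With an estimated correlation their adjusted p was 0.507 each, and neither passed without DF19-9-11T (camera adjusted p = 0.0563 and 0.128). Of their members only ATF3 and TRIB3 passed with any line left out. Without DF19-9-11T edgeR adjusted p was 0.118 for FOSB, 0.165 for JUN, 0.145 for XBP1 and 0.0889 for PDIA4.

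Lists that did not pass held, as higher and lower members, 2 higher, among them FABP7, against MAL, ERBB3 and CDH19 of 10 Schwann and glial genes, KIT and EDNRB of 5 melanocyte genes, and ALPL against ACAN, COL2A1, COL9A3, RUNX2 and COL11A1 of 8 cartilage and bone genes. LIN28A was lower of 6 pluripotency genes, CD68 higher of 3 immune cell genes and HOXA2 lower of 6 anterior HOX genes. PECAM1, TEK and ESAM were higher and ERG lower of 9 endothelial genes. PECAM1 was near the floor, with 59 counts over the GFP-positive libraries and 15 over the GFP-negative ones. IFIT2 and IFIT3 were higher and IFI44 (3 counts against 95), IFI44L, USP18 and IFI6 lower of 16 interferon-stimulated genes. PMEPA1, IGFBP3 and LTBP2 were higher and TGFBI, THBS1 and SKIL lower of 11 TGF-beta response genes. Adjusted over the list alone, 5 Schwann and glial genes and 1 melanocyte gene were lower, and the other counts stayed. ESAM (5.74 ± 0.51) and TEK (4.63 ± 0.88) rose most and ERG (-4.99 ± 0.59) fell in the endothelial list. IFIT2 (5.91 ± 0.50) rose most in the interferon list. Calls lost with a line left out, each with its edgeR adjusted p, were FABP7 (0.13), KIT (0.0645), THBS1 (0.0613 without WTC11), COL9A3 (0.0557 without IMR90-4), LIN28A (0.0736), PECAM1 (0.117), CD68 (0.116), HOXA2 (0.091), IFI44 (0.0843) and IFI44L (0.0835).

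In all, 3617 of 17222 genes differed, 1861 higher and 1756 lower, and 3589 of them had the same sign in all 4 lines, which a test with the line as a block favours. Of all tested genes, 57.5% had the same sign in all 4 lines, against 12.5% for random signs. Among the largest rises were TAL1, a blood-lineage transcription factor (7.84 ± 0.69), NMNAT2 (7.56 ± 0.59), MMP9, a matrix protease (7.48 ± 0.52), COL5A3 (7.20 ± 0.71) and CAV1, caveolin (7.16 ± 0.62). Besides PDGFRA, the largest falls of genes with a mean log2 CPM of at least 2 included ECEL1 (-6.64 ± 0.64), TGFBI (-5.76 ± 0.42), ISLR2 (-5.69 ± 0.70), SMOC1 (-5.57 ± 0.48), CLMP (-5.57 ± 0.25), RET, the receptor for GDNF (-5.50 ± 0.87), and EYA2 (-5.46 ± 0.96), with edgeR adjusted p from 6.17e-06 to 0.00265. The changes of any 2 lines correlated at a mean Pearson r of 0.759 across genes, which are not independent replicates. The count was 1987 genes without DF19-9-11T, 2120 without H9, 1899 without IMR90-4, 6465 without the WTC11 neural crest library and 6699 in a fit to the 8 sorted libraries alone.

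**Figure D4:**
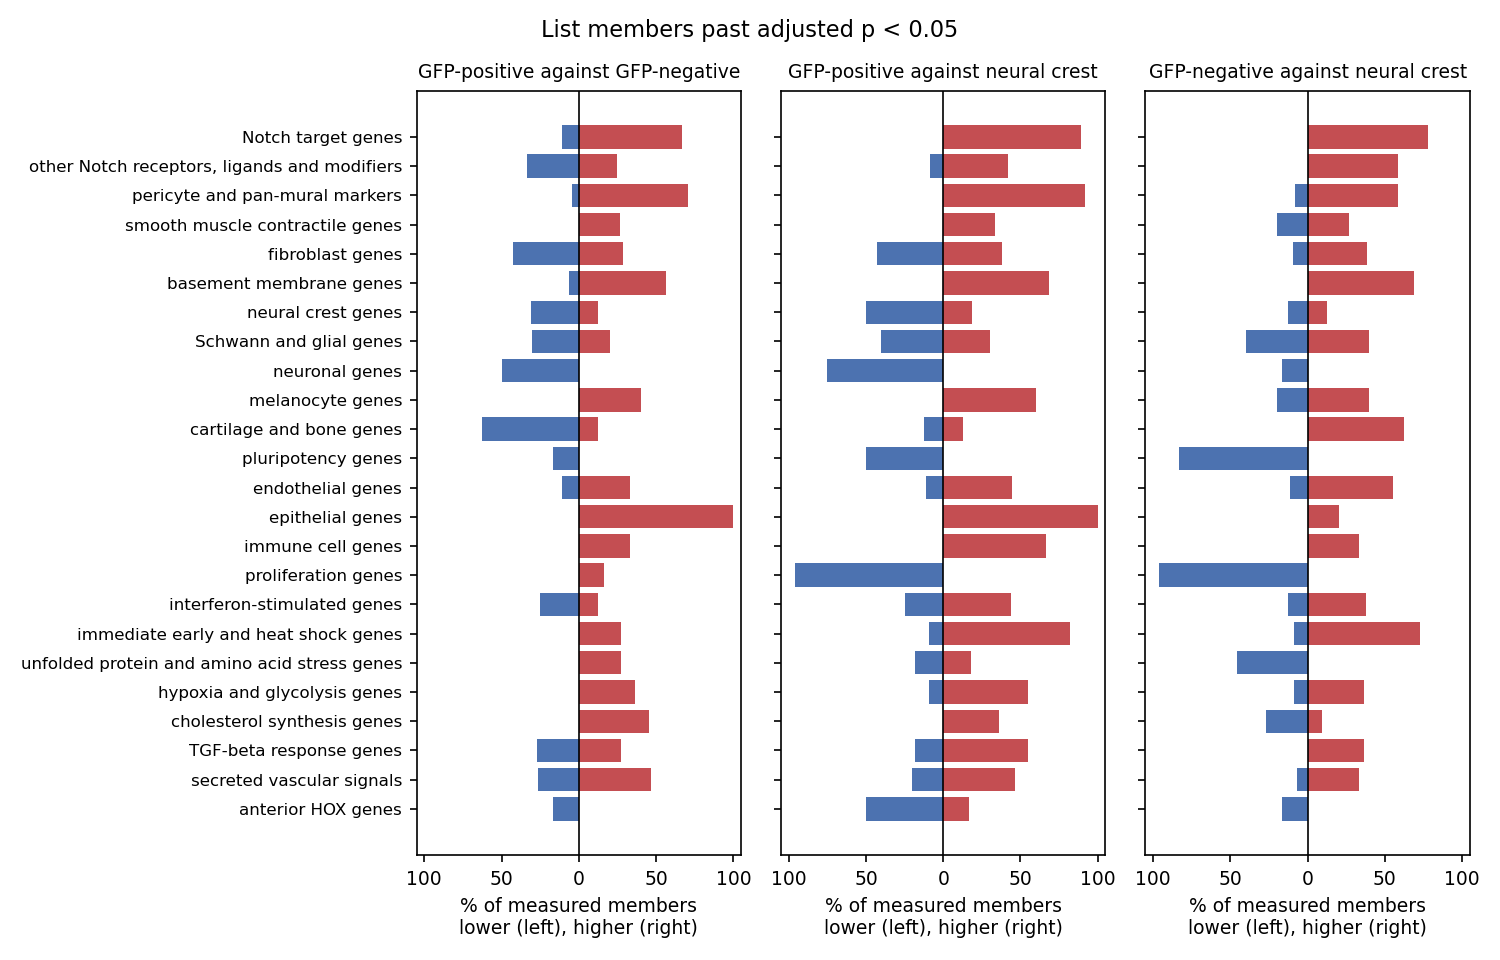
Share of the measured members of each of the 24 lists that were higher (right, red) or lower (left, blue) in each comparison, as a percent of the members measured. Of the 25 proliferation genes, 24 are lower in both sorted fractions than in neural crest, and of the 24 mural markers 17 are higher in GFP-positive than in GFP-negative cells.

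GFP-positive cells were also compared with the neural crest of the same differentiation, a contrast that holds the vector, 6 days of further culture and the sort together. Mural markers and Notch target genes were higher in GFP-positive cells and proliferation genes were lower. Of 24 mural markers, 22 were higher and none lower (camera adjusted p = 2.46e-22, and adjusted p = 0.0672 with an estimated correlation). Of 9 Notch target genes, 8 were higher (camera adjusted p = 1.72e-07, and adjusted p = 0.149 with an estimated correlation), and the ninth, HES1, stood at 0.47 ± 0.77 (edgeR adjusted p = 0.631, and 0.0284 without DF19-9-11T). Of 25 proliferation genes, 24 were lower (camera adjusted p = 3.06e-11, and adjusted p = 0.149 with an estimated correlation).

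PDGFRB rose by 2.69 ± 0.30, RGS5 by 2.62 ± 0.61 and KCNJ8 by 3.63 ± 0.26, with edgeR adjusted p from 5.64e-06 to 0.00484. NDUFA4L2, a mitochondrial protein enriched in pericytes, rose by 9.30 ± 0.34. GJA4 had 1 count in neural crest, a ratio of 18500 (95% interval 3320 to 731000). FOXF2 had a ratio of 2930 (811 to 24200), and COX4I2, with no neural crest counts, was at least 1630-fold higher. Among Notch targets, NRARP (9.14 ± 0.76), HES4 (7.76 ± 0.47), DTX1 (5.83 ± 0.81) and HEYL (5.26 ± 0.53) rose most, with edgeR adjusted p from 2.72e-06 to 2.79e-04. DLK1 (6.70 ± 0.79), NOTCH1 (3.74 ± 0.42) and DLL4 (3.62 ± 0.56) rose and DLL3 (-3.73 ± 0.53) fell among the other Notch genes.

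Basement membrane genes were higher in 11 of 16 and lower in none (camera adjusted p = 4.71e-07, and adjusted p = 0.27 with an estimated correlation), led by LAMA4 (6.64 ± 0.63), COL18A1 (5.49 ± 0.52) and COL4A1 (4.56 ± 0.50). Fibroblast genes went both ways, 8 higher and 9 lower of 21 (10 lower adjusted over the list alone), with COL1A1 at 4.91 ± 0.42 and PDGFRA at -5.16 ± 0.44, and the list did not pass. Of 15 smooth muscle genes, 5 were higher, among them MYLK (3.50 ± 0.48) and LMOD1 (2.56 ± 0.48), and the list did not pass. ACTA2 stood at 0.81 ± 0.37 (edgeR adjusted p = 0.0944, and 0.0103 without IMR90-4) and TAGLN at -0.88 ± 0.79 (edgeR adjusted p = 0.375, higher in 2 of 4 lines). NGFR fell from 900 TPM ± 556 (n = 4) to 39.1 ± 37.5 (n = 4), by 5.05 ± 0.67 on the log2 scale (edgeR adjusted p = 2.12e-04). Of 16 neural crest genes, 8 were lower and 3 higher (9 lower adjusted over the list alone), and neither SOX10 (-0.99 ± 0.40, edgeR adjusted p = 0.0615, and 0.0183 without WTC11) nor the list passed. Neuronal genes were lower in 9 of 12 (10 adjusted over the list alone; camera adjusted p = 0.0101, and adjusted p = 0.456 with an estimated correlation), with ELAVL4 at -4.32 ± 0.78 and ISL1 at -3.91 ± 0.89.

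Of 11 immediate early and heat shock genes, the former induced within minutes by growth factors and by handling of cells, 9 were higher and the heat shock gene DNAJB1 was lower (camera adjusted p = 5.71e-05, and adjusted p = 0.306 with an estimated correlation). FOS went from 1.15 TPM ± 0.642 (n = 4) to 652 ± 377 (n = 4), a log2 fold change of 8.66 ± 0.69, and EGR1 (8.31 ± 1.16) and FOSB (8.27 ± 0.92) followed, with edgeR adjusted p from 1.19e-05 to 2.80e-04. The hypoxia and glycolysis list also passed, with 6 of 11 higher and ADM lower (camera adjusted p = 0.00464, and adjusted p = 0.27 with an estimated correlation), led by ENO2 (4.91 ± 0.47), NDRG1 (4.87 ± 0.44) and SLC2A1 (4.76 ± 0.44). Secreted vascular signals were higher in 7 of 15 and lower in 3 (camera adjusted p = 0.0154, and adjusted p = 0.149 with an estimated correlation), with ANGPT2 at 8.91 ± 0.60 and TGFB1 at 5.37 ± 0.25. All 5 measured epithelial genes, of 10 in the list, were higher (camera adjusted p = 0.0196, and adjusted p = 0.27 with an estimated correlation). Without a filter on low counts neither of these 2 lists passed (camera adjusted p = 0.121 and 0.06).

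In all, 8896 genes differed, 4330 higher and 4566 lower. MMP9 (12.95 ± 0.71), FOXQ1 (11.88 ± 0.84), SPON2 (11.42 ± 0.74), PLXDC1 (11.28 ± 0.69) and TAL1 (11.17 ± 0.84) were among the largest rises, and RASAL1 had a ratio of 4850 (1660 to 23500). ISLR2 (-7.05 ± 0.75), GJA1, the gap junction protein connexin 43 (-6.49 ± 0.42), CLMP (-5.97 ± 0.25), GPR160 (-5.32 ± 0.55), ATOH8 (-5.30 ± 0.58), ST6GALNAC5 (-5.26 ± 0.66) and TRIL (-5.14 ± 0.52) were, with PDGFRA, among the largest falls of genes with a mean log2 CPM of at least 2, with edgeR adjusted p from 1.33e-06 to 1.54e-04. Without the WTC11 neural crest library 9710 genes and 9 lists passed. The vector, the time in culture and the sort cannot be told apart in this comparison.

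GFP-negative cells were compared with neural crest to see what differs in cells of the transduced culture that lack the reporter. Proliferation genes were lower in 24 of 25 (camera adjusted p = 2.63e-22, and adjusted p = 0.0997 with an estimated correlation), led by RRM2 (-4.28 ± 0.30), PCNA (-3.54 ± 0.38) and CCNB1 (-3.22 ± 0.36). Notch target genes were higher in 7 of 9 and mural markers in 14 of 24, with 2 of the latter lower, in cells with little reporter. HES1 rose from 33.3 TPM ± 7.31 (n = 4) to 1452 ± 980 (n = 4) and HEY1 from 16.4 ± 18.4 (n = 4) to 508 ± 247 (n = 4).

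Among Notch targets, NRARP (5.58 ± 0.66), HEY1 (4.93 ± 0.59), HES1 (4.33 ± 0.81), HES4 (4.13 ± 0.40) and HEYL (3.37 ± 0.48) rose, with edgeR adjusted p from 8.74e-05 to 0.00182 (camera adjusted p = 8.19e-05, and adjusted p = 0.315 with an estimated correlation). Of 12 other Notch receptors, ligands and modifiers, 7 rose and none fell, among them the ligand JAG2 (3.69 ± 0.53) and MFNG (3.73 ± 0.93) (camera adjusted p = 0.0276, and adjusted p = 0.589 with an estimated correlation). Mural markers passed as a list (camera adjusted p = 9.95e-05, and adjusted p = 0.315 with an estimated correlation). PTH1R (5.95 ± 0.56), SLC6A12 (5.20 ± 0.52) and PDGFRB (1.90 ± 0.29) rose, with edgeR adjusted p from 7.56e-05 to 6.65e-04. COX4I2 was at least 17.2-fold higher and GJA4 had a ratio of 107 (95% interval 18.8 to 4280). RGS5 fell by 2.08 ± 0.62 (edgeR adjusted p = 0.018; 0.0948 without IMR90-4 and 0.0707 without WTC11), TBX2 fell, and KCNJ8 stood at 0.12 ± 0.24 (edgeR adjusted p = 0.703).

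Basement membrane genes were higher in 11 of 16 (12 adjusted over the list alone), with LAMA5 (3.76 ± 0.68) and LAMA4 (3.07 ± 0.53) in front (camera adjusted p = 0.00247, and adjusted p = 0.589 with an estimated correlation). Of 21 fibroblast genes, 8 were higher and LUM and THY1 lower, with COL1A1 at 3.67 ± 0.40 and MFAP4 at 3.19 ± 0.59, and PDGFRA at 0.76 ± 0.36 did not pass (edgeR adjusted p = 0.102, and 0.0368 without DF19-9-11T). The fibroblast list did not pass. Of 15 smooth muscle genes, DES (4.34 ± 0.79), LMOD1 (3.45 ± 0.49), TPM1 and TPM2 rose and TAGLN (-3.23 ± 0.83), MYL9 and CALD1 fell. TAGLN did not pass without IMR90-4 (edgeR adjusted p = 0.0712), nor TPM1 without H9 (edgeR adjusted p = 0.0535). ACTA2 stood at -0.27 ± 0.37 (edgeR adjusted p = 0.566), and that list did not pass either. NGFR fell by 1.79 ± 0.58 (edgeR adjusted p = 0.0254; 0.0998 without DF19-9-11T and 0.0856 without IMR90-4) and SOX10 was 0.28 ± 0.40 (edgeR adjusted p = 0.587). Of 16 neural crest genes, TFAP2A (1.81 ± 0.48) and MSX2 were higher and NGFR and PAX3 lower, none of them adjusted over the list alone, and the list did not pass. MSX2 did not pass without DF19-9-11T (edgeR adjusted p = 0.203) or H9 (0.0551), nor PAX3 without H9 (0.0913), IMR90-4 (0.13) or WTC11 (0.0859).

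Of 11 immediate early and heat shock genes, 8 were higher and DNAJB1 was lower in GFP-negative cells too (9 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.00204, and adjusted p = 0.589 with an estimated correlation), with FOS at 7.19 ± 0.66 and EGR1 at 6.94 ± 1.13. The cartilage and bone list passed upward with 5 of 8 members (camera adjusted p = 0.0491, and adjusted p = 0.315 with an estimated correlation), among them the cartilage proteoglycan ACAN (3.43 ± 0.59) and RUNX2, a bone transcription factor (2.76 ± 0.45). The pluripotency list passed downward with 5 of 6 (camera adjusted p = 0.0491, and adjusted p = 0.315 with an estimated correlation), among them LIN28A (-1.92 ± 0.27). The unfolded protein list passed downward with 5 of 11 (camera adjusted p = 0.0491, and adjusted p = 0.618 with an estimated correlation), led by SDF2L1 (-1.45 ± 0.17). The TGF-beta list passed upward with 4 of 11 (camera adjusted p = 0.0428, and adjusted p = 0.589 with an estimated correlation), led by LTBP2 (4.04 ± 0.44). None of these 4 lists passed without the WTC11 neural crest library, nor did the cartilage and bone list without a filter on low counts (camera adjusted p = 0.067).

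In all, 8599 genes differed, 4397 higher and 4202 lower. PTGDS, a prostaglandin synthase (7.84 ± 0.60), SLC16A3, a lactate transporter (7.27 ± 0.40), ARC, an immediate early gene (6.53 ± 0.90), FOXQ1 (6.38 ± 0.80) and the pseudogene FER1L4 (6.27 ± 0.54) were among the largest rises, and RASAL1 had a ratio of 481 (164 to 2330). DNA replication genes CDC45 (-4.30 ± 0.43), PCLAF (-4.13 ± 0.40), CDC6 (-3.92 ± 0.32), GINS2 (-3.89 ± 0.47) and EXO1 (-3.85 ± 0.28) were among the largest falls, with NME1 (-4.25 ± 0.48) and LPL, lipoprotein lipase (-4.15 ± 0.91), and had edgeR adjusted p from 3.62e-05 to 0.00408. Without the WTC11 neural crest library 9057 genes and 6 lists passed. Time in culture, exposure to the virus, culture together with GFP-positive cells and the sort cannot be told apart here. eGFP passed with 4.37 ± 1.29 (edgeR adjusted p = 0.0172), but not without DF19-9-11T (0.0671), H9 (0.0614) or WTC11 (0.0507).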

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

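Of 87 groups of 4 libraries examined, library measures and the TPM of genes whose levels are given, 14 held a library far from the other 3; chance gives about 1 in 20 groups. The number is no test against chance, since many of these genes were chosen for their values, SPP1 and ANXA1, which hold 3 of the 14, because the WTC11 neural crest library stood out in them. All tests in this part were chosen after the result was seen.

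In GFP-positive cells, MMP9 was 16757 TPM in DF19-9-11T and 172 to 475 in the other lines, and in GFP-negative cells it was 122 in DF19-9-11T and 1.53 to 3.28 in the others. In neural crest it was 1.00 TPM in that line and 0.0871 to 0.121 in the others. In GFP-negative cells of that line CSAG1 was 2.58 TPM against 1.06 to 1.29, and ANXA1 was 1.92 against at most 0.292. In the IMR90-4 neural crest library, eGFP was 5.37 TPM and 0 in the others, RGS5 was 31.5 against 2.22 to 6.33, and FOXE3 was 3.59 against 0.0778 to 0.487. That library held 19.77 M counts against 20.13 to 20.16 M (1 M is 1000000).

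The WTC11 neural crest library stood apart, with a TMM factor of 0.6492 against 0.9663 to 1.013. SPP1 was 296 TPM in it against 0.91 to 32.7 in the other lines, ANXA1 was 235 against 2.14 to 14.8, and HES1 was 22.4 against 35.6 to 37.9. KISS1 was 0.427 TPM against 0, which rests on 3 counts. NGFR was 149 TPM against 817 to 1380 and TFAP2A 0.824 against 36.6 to 56.4. Against the mean of the other lines on TMM-scaled log2 CPM, where the median of all tested genes was -0.04, neural crest genes went both ways (9 of 16 lower, median -0.12). Neuronal genes (10 of 12 lower, median -2.66), cartilage and bone genes (7 of 8, -1.20) and Notch target genes (7 of 9, -0.96) were mostly lower. Of the others, 16 of 24 mural markers, 5 of 10 Schwann and glial genes, 9 of 25 proliferation genes and 1 of 5 epithelial genes were lower. Tallies depended on the scale. On log2(TPM + 1), which keeps a factor shared by all genes, 15 of 16 neural crest genes (median -1) and 18 of 25 proliferation genes (median -0.56) were lower. In TPM, KRT8, KRT18, S100B and CDKN2A, chosen after their values were seen, were higher in it than in each of the other neural crest libraries.

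A few genes taking most of the counts would lower all others by the same factor and leave their order as it is. Over the 11594 genes with a mean log2 CPM of at least 2 outside its 50 highest, its Spearman r with the other neural crest libraries was at most 0.839, against 0.925 to 0.962 among those, which argues against this as the whole cause. Its depth was 101% of the mean of the others. Its deviations correlated with those of the other WTC11 libraries at 0.353 or more, above the highest value for pairs of different lines (0.0962), which argues against a wrong line label. A different state of the cells at harvest, or a culture that held other cells, stays open as a candidate explanation. No biological explanation was tested, as each line has 1 neural crest library.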

How the results depend on the processing

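Leaving out the WTC11 neural crest library and leaving out genes listed several times were chosen after seeing the data. For single named genes, 2864 values under alternatives kept their direction and side of the threshold, 274 no longer passed, 24 newly passed and 7 reversed; for lists, 288 kept their call and 53 lost it.

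GFP-positive against GFP-negative, 3617 genes by the edgeR fit, gave 1899 to 6465 with a library or line left out, 6699 in a fit to the 8 libraries alone, 1357 in a test against a log2 fold change of 1, and 3066 to 4843 under the other alternatives that kept the replicate block. Without the block it gave 2471 genes and 13 lists, and the counts against neural crest became 7838 and 7274. Of single named genes, 18, 16 and 16 lost their call without it in the 3 comparisons. Against a log2 fold change of 1, the counts against neural crest were 3603 for GFP-positive and 2896 for GFP-negative cells; other alternatives gave 6476 to 9741 and 6282 to 9570. A test against a larger change passes fewer genes by construction. The 6465 genes came from leaving out only the WTC11 neural crest library, which belongs to neither of the 2 groups compared there. Its place in the shared fit thus lowered that count, by a step that was not tested. For the others the cause was not tested.

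With an estimated correlation 1, 0 and 0 lists passed in place of 12, 9 and 10. fry, which does not compare a list with other genes, passed 15, 20 and 17. For GFP-negative cells against neural crest, 6 to 10 lists passed with a library or line left out. The mean correlation of the lines was 0.759, 0.786 with a prior count of 2 and 0.847 over genes with a mean log2 CPM of at least 2.

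On the log2(TPM + 1) scale the median of all genes moved to -0.23 (GFP-positive against GFP-negative), 0.17 (GFP-positive against neural crest) and 0.44 (GFP-negative against neural crest), from -0.03, -0.03 and 0.09. The share of higher calls moved from 51.5%, 48.7% and 51.1% to 34.1%, 57.1% and 71.7%, and with 0.1 added to 35.5%, 57.2% and 71.6% (medians -0.26, 0.22 and 0.55). The TPM values were not scaled between libraries by TMM. Mean TMM factors were 0.908 in neural crest, 1.153 in GFP-negative and 0.971 in GFP-positive cells. The medians moved in the direction that this lack of scaling gives, and whether it accounts for the whole shift was not tested. Without a filter the medians of the edgeR fit against neural crest were 0.15 and 0.25. On the log2(TPM + 1) scale no list that passed changed the sign of its median; 6 lists that did not pass did. Without a filter the fibroblast list, GFP-positive against GFP-negative, lost its call (camera adjusted p = 0.324) and its median went from -0.63 to 0.084.

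Single genes whose value changed sign were all genes that did not pass. With a line left out, HES1, GFP-positive against neural crest, ranged from -0.31 to 1.59 and TAGLN, GFP-positive against neural crest, from -1.63 to 0.13. KCNJ8, GFP-negative against neural crest, ranged from -0.046 to 0.25, ACTA2, GFP-negative against neural crest, from -0.60 to 0.19 and SOX10, GFP-negative against neural crest, from -0.25 to 0.58. ACTA2 was 0.32 there on the log2(TPM + 1) scale. The cause was not tested. Calls gained by genes named whatever their p, besides those with a line left out, were PDGFRB, ACTA2, TAGLN and SOX10 by DESeq2 and SOX10 on log2(TPM + 1), GFP-positive against GFP-negative (adjusted p = 0.0154, 0.0206, 0.00264, 0.0147 and 0.0445). PDGFRB, ACTA2 and TAGLN also passed there with 8 libraries (edgeR adjusted p = 0.00402, 0.00465 and 0.0083) and without the WTC11 neural crest library (0.0017, 0.0345 and 0.0225). Against neural crest they were ACTA2 by DESeq2 (0.0424) and on log2(TPM + 1) (0.0466) and SOX10 with 8 libraries (0.0301) in GFP-positive cells, and KCNJ8 (0.0354) and PDGFRA (0.0129) on log2(TPM + 1) in GFP-negative cells. Lines were left out for at most 4 members of each list, so other members named were not examined in this way. Log2 changes of 1 were mostly missed in the simulation, where few genes were changed, and this does not carry over to the real comparisons. Of the protein-coding names listed several times, 70.4% hold fewer than 50 counts.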

Other observations

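Some of the largest changes lay outside the fixed lists, in genes chosen after their values were seen. GFP-positive cells expressed KISS1, the kisspeptin precursor, at 1431 TPM ± 645 (SD, n = 4) against 7.62 ± 7.18 (n = 4) in GFP-negative cells, a log2 fold change of 8.23 ± 0.56 (edgeR adjusted p = 1.40e-05). CBLN1, a secreted organiser of synapses, reached 1015 TPM ± 536 (n = 4) against 33.9 ± 46.8 (n = 4), a change of 6.13 ± 0.94 (edgeR adjusted p = 0.00125). SOX1, a transcription factor of neural progenitors, stood at 286 TPM ± 34.5 (n = 4) and 5.55 ± 3.52 (n = 4), and FOXE3, a forkhead factor of the lens, at 194 ± 95 (n = 4) and 2.04 ± 0.266 (n = 4). FN1, fibronectin, stood at 2999 TPM ± 1100 (n = 4) and 90.1 ± 36.4 (n = 4), and KCNK3, an acid-sensitive potassium channel, at 106 ± 49.1 (n = 4) and 5.18 ± 5.44 (n = 4). CSAG1, a cancer/testis gene with close paralogs, was 241 TPM ± 40 (n = 4) in GFP-positive and 1.50 ± 0.728 (n = 4) in GFP-negative cells and is listed at 0 in neural crest.

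GFP-negative cells of all 4 lines had high levels of some skeletal muscle genes. TNNC2, the troponin C of fast muscle, was 531 TPM ± 246 (n = 4) there, 35.2 ± 35 (n = 4) in neural crest and 11.1 ± 3.23 (n = 4) in GFP-positive cells, and ACTN3, the actinin of fast muscle, was 390 ± 228 (n = 4), 11.4 ± 8.45 (n = 4) and 18.3 ± 8.91 (n = 4). ENO3, muscle enolase, was 306 TPM ± 60.9 (n = 4), 31.6 ± 27.3 (n = 4) and 13.1 ± 5.24 (n = 4). In a list of 36 skeletal muscle genes written after these values were seen, 18 of 27 measured members were higher in GFP-negative cells than in neural crest and none was lower, and 15 were lower and 2 higher in GFP-positive than in GFP-negative cells.

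The tests in the rest of this part were chosen after the results were seen. Skeletal muscle cells in the GFP-negative fraction would bring the genes of the muscle filaments (myosins, skeletal actin, titin and nebulin), which are among the most abundant in such cells. The 10 filament genes had a median of 0.293 TPM in GFP-negative cells and a mean of at most 12.7 TPM, in ACTA1 (23.1 in the highest library). The troponins, also filament proteins, were counted with the other members and not with these 10. Among the other members, those that were higher, TNNC2, TNNT1 and TNNT3 among them, had a median of 39.0 TPM. That median is high by this choice. Other measured members that were not higher, from 0.0352 TPM in TRDN to 23.5 in TNNI1, were left out, so the medians do not decide the question. ACTA1 (3.24 ± 1.01, edgeR adjusted p = 0.0221) and NEB (2.37 ± 0.56, edgeR adjusted p = 0.0058) were themselves higher than in neural crest, while MYH1, MYH2, MYH8 and MYL1 were at 0 TPM. Of the other myosin genes, MYH7 was at 0.0395, MYH3 at 1.39 and MYLPF at 3.74 TPM in GFP-negative cells. MYH3 and MYLPF did not pass against neural crest, and MYH7 was not tested. MYOD1 (1.29 TPM) and MYOG (0.575 TPM), at 0 in neural crest, were not tested either. The low levels of all these myosin genes argue against mature muscle cells as the main source of TNNC2 at 531 TPM. They say less about the other members, and nothing about less mature muscle cells. The sort was for GFP only and would not remove such cells, and a partial muscle programme in the cells of the fraction may be a candidate explanation that was not tested.

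Mural and Notch target genes were higher in GFP-negative cells than in neural crest, and GFP-positive cells that slipped into the fraction could be a source. The eGFP of GFP-negative cells was 0.182% to 1.07% of that of GFP-positive cells. The excess over neural crest was a median of 17.0 times what this share predicts for the 14 mural markers that were higher, and over 2 times in all 4 lines for 10 of them; for the 7 Notch target genes the median was 61.5 times, and all 7 exceeded 2 times in all 4 lines. Only members that passed as higher were used, which favours a large excess, so these medians do not speak for the whole lists. Of the mural markers, 2 were lower and 8 did not pass, and 2 Notch target genes did not pass. For GJA4, FOXF2, COX4I2 and HIGD1B the excess was 0.827 to 1.79 times the prediction, so for these 4 genes carried-over cells stay open. A larger share of cells like the GFP-positive ones, with little eGFP, would need about the same share for every gene. Over the same members that passed as higher, the upper quartile of the share needed was 25.2 times the lower. This speaks only to cells with the full GFP-positive profile. NOTCH3 was 289 TPM in GFP-negative cells and 47.4 in neural crest, and its counts do not separate vector from endogenous reads. Low vector expression in GFP-negative cells stays open and untested, as do signals from neighbouring cells, the culture medium and time in culture.

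Other splits of the same libraries were counted. With the line ignored, 1 of the 35 splits of the 8 libraries, the real one, gave as many genes in each comparison. The counts were 4253 for GFP-positive against GFP-negative (highest other 60), 6167 for GFP-positive against neural crest (highest other 17) and 5909 for GFP-negative against neural crest (highest other 25). These splits ignore that the libraries come in pairs of the same line, so they cannot exclude chance. For the number of lists passed, 1 of 35 splits gave as many in the first comparison (13, highest other 10). It was 13 of 35 in the second (8, highest other 14) and 19 of 35 in the third (7, highest other 12). Chance is thus not excluded for the number of lists. Splits other than the real one passed up to 10, 14 and 12 lists while passing 0 genes. A camera call with the preset correlation therefore does not exclude chance for a single list in any comparison. Libraries of the same line resemble each other, and with the line as a block there are 8 splits within lines, too few for a share under 0.05. The real values were 6699, 6476 and 6711 genes (1 of 8 each, highest other 0) and 12, 13 and 9 lists (1, 2 and 2 of 8, highest other 9, 13 and 11).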
